A study of Homo sapiens with 3 samples.

How the data were processed

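Total RNA of MDA-MB-231 cells was extracted with Trizol, and biotin-labelled sense cDNA was prepared with whole-transcript GeneChip kits, per the labels' protocols. Each of the 3 groups, DMSO control, CFX and Mt-CFX, was 1 array. The deposited values were log2 expression values per probe set, made with RMA in Affymetrix Expression Console, per the submitters' processing notes. No version, annotation release or genome build was given in the sources used here. The log2 scale was checked on the values, which ran from 0.0868 to 13.1. As background, RMA corrects each array for background, gives all arrays the same distribution of probe values, and summarises the probes of a probe set by a median polish across the arrays of the run. The sorted values of any pair of arrays lay at most 0.244 log2 apart, so differences in the total amount of RNA between samples are not visible in these data. A further property bears on every value below. Of all probe sets, 49.5% had exactly the same value on all 3 arrays, as did 45.3% of the genes compared, so that medians of gene lists are often exactly 0.

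Probe sets were named from the platform annotation provided with the values, which gave 1 gene symbol to 16098 probe sets and several symbols to 0. The other 37519 probe sets were unnamed here and entered no comparison of genes. All named probe sets matched the reference gene table by gene ID, and 0 symbols needed an update. The named probe sets stood for 14884 genes, of which 11916 were protein-coding. Where a gene had several probe sets, which held for 487 genes, the one with the highest mean over the 3 arrays was used. Genes were kept when the highest of the 3 arrays reached the median of all probe sets, 3.89 log2, which left 8868 protein-coding genes. No coordinates are given, since the build of the array annotation is not stated.

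Differences of log2 values were taken for CFX over control, Mt-CFX over control and Mt-CFX over CFX. With 1 array per group there is no replicate error, so no test was made and no p-value is given. Genes were counted by a fixed size of 2-fold, with 1.5-fold as an alternative. For gene groups, 42 lists were fixed, and 31 of them had at least 5 members above the floor. Their medians were placed among 10000 random lists of the same size, drawn from 20 bins of mean expression, and the percentile describes these arrays and is not a p-value. The mean of each list was placed in the same way. Of the 1091 genes in the lists 585 were measured here, and lists such as the proteasome, complex I, mitochondrially encoded and replication histone genes had no named member and were not analysed here.

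Named genes followed a rule: the 10 highest and 10 lowest protein-coding genes of each comparison, up to 4 members of each list that stood apart, members of other lists with a difference of at least 1.5-fold, and 26 preset genes whatever their values. Of these preset genes, TOP1MT, POLG, TFAM, CDKN1A, MMP2, MMP9, CDH1, CDH2 and IL6 were not analysed here, since no probe set was named for them, and CXCL8 was below the floor. The groups, comparisons, gene lists, naming rule and alternatives were fixed before the data were examined, except that genes of every type were added later as an alternative for the overlap of the compounds.

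The agreement of the compounds was described by Pearson's r, Spearman's rho and the covariance across genes, beside 100 simulated data sets with no effect and a shared control, in which each array had an SD of 0.0666 log2. The counting and the list percentiles were tested on simulated data for CFX over control, with 8868 genes of which 200 were changed and an SD of 0.0942 log2. Of genes changed by 1.5 log2, 100% were counted at 2-fold, of genes changed by 0.6 log2 0% were, and of unchanged genes 0%. Of 200 random lists of 20 genes with no shift 2.00% stood apart, and of those shifted by 0.1 log2 93.0% did. The self-test used fewer random draws per list. These simulations have no ties and do not stand for the variation between repeats.

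Alternatives were no floor, a floor on the mean of the 3 arrays, a floor at the 75th percentile, the mean of a gene's probe sets, re-centring by a lowess curve on mean expression with a span of 0.3 (which moved no gene in Mt-CFX over control), probe sets of every gene type, 1.5-fold, 5 expression bins, and list means. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9. The number of arrays limits the precision of the values, the ties limit what can be read from small differences, and probe-level data were not used here.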

Results

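Gene expression was measured in MDA-MB-231 cells, an established human triple-negative breast cancer line that is widely used as a model of invasive disease. The cultures were kept for 72 h with 10 µM CFX, with 10 µM Mt-CFX, or with 1% DMSO, the solvent used as the vehicle control. The labels give a DMSO content for the control alone, so a difference from the control may include an effect of DMSO. The series title names ciprofloxacin, a fluoroquinolone antibiotic whose bacterial targets are the type II topoisomerases, and Mt-CFX is known here only by its code name. Each of the 3 groups was 1 array (n = 1), so no value has a replicate error, no p-value could be computed, and no difference below was checked against the spread between repeats. The design implies 3 comparisons: each compound against the vehicle, and the compounds against each other at the same dose and time. The values were log2 expression values per probe set, and 8868 protein-coding genes were compared. The median of all probe sets was 3.91 on the control array and 3.88 on the Mt-CFX array, with the CFX array between them. Genes were counted when the arrays differed at least 2-fold. Gene lists were described by their median log2 difference, and a list was said to stand apart when this median lay in the lowest or highest 0.5% of 10000 random lists matched on expression. If the 31 lists large enough to place were independent random draws of genes, 0.31 would stand apart in each comparison. The lists share members, however, and genes of a list may vary together between cultures, so 0.31 is not a value for no effect. In the self-test, random lists with no shift also stood apart at a higher rate than this. Since 45.3% of the genes had exactly equal values on all 3 arrays, the median of a random list was often 0, and a median very close to 0 could stand apart. The mean of each list was therefore placed as well.

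With CFX, the clearest group difference from the vehicle control was in the cytosolic aminoacyl-tRNA synthetases, the enzymes that load amino acids onto tRNAs, which were higher by a median of 0.16 log2 over 17 genes. Targets of ATF4, the transcription factor at the centre of the integrated stress response, were higher by a median of 0.031 and a mean of 0.11 log2 over 19 genes, a placement that was lost with no floor and with the mean of each gene's probe sets. Genes of fatty acid synthesis were lower, with a median of −0.023 and a mean of −0.052 log2 over 12 genes. At the 2-fold size, 2 genes were higher with CFX, ZNF836 and SPN, and 0 genes were lower.

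Among the aminoacyl-tRNA synthetases, 11 of 17 members were higher with CFX, 2 were lower and 4 had equal values, and the median lay above all 10000 random lists. YARS1 was higher by 0.36 log2, MARS1 by 0.30, GARS1 by 0.24 and CARS1 by 0.21. In the ATF4 list 11 of 19 members were higher, 3 were lower and 5 were equal, and the median stood at the 99.6th percentile. CTH, which makes cysteine from cystathionine, was higher by 0.67 log2, a 1.59-fold difference. PSAT1, an enzyme of serine synthesis, was higher by 0.40, the secreted stress cytokine GDF15 by 0.32, and DDIT4, an inhibitor of mTOR signalling, by 0.30. In the fatty acid synthesis list 6 of 12 members were lower, 1 was higher and 5 were equal, with the median at percentile 0.0700. FASN, the fatty acid synthase, had a log2 difference of −0.28, FADS1 of −0.09, FADS2 of −0.08 and ACLY of −0.07.

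Another 3 lists stood apart with CFX by their medians and not by their means. DNA damage response and repair genes had a median of 0.074 log2, with 12 of 19 members higher and 1 lower, and the mean lay at percentile 97.3. RAD50 was higher by 0.19, MRE11 by 0.16, RAD51C by 0.13 and EXO1 by 0.13. Glycolysis genes had a median of −0.029 over 8 members, led by GPI at −0.12, with LDHA at −0.07, HK2 at −0.06 and PGK1 at −0.06, and their mean lay at percentile 3.40. Hypoxia targets had a median of −0.0058 and a mean at percentile 1.14, with 9 of 18 members lower, 3 higher and 6 equal. CA12 was at −0.28, EGLN3 at −0.23, STC2 at −0.20 and NDRG1 at −0.17. The higher members were DDIT4 at 0.30, MXI1 at 0.16 and ERO1A at 0.04, and DDIT4 and STC2 are also in the ATF4 list. The CFX value of EGLN3 lay below the floor, so the size of its difference is uncertain. Targets of NF-kB and extracellular matrix genes stood apart by their means only, at −0.074 log2 over 16 genes and −0.078 log2 over 10 genes.

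ZNF836, a zinc finger gene, was at 4.44 with CFX and 3.17 in the control, a 2.42-fold difference. SPN, which encodes the cell surface sialoglycoprotein CD43, was at 3.93 against 2.67, a 2.38-fold difference. After these genes and CTH the next highest differences were those of BEND7 at 0.63, the receptor gene NOTCH3 at 0.58, PRB2 at 0.56, PVRIG at 0.55, UBE2D4 at 0.54, LCE4A at 0.53 and KLHDC7B at 0.51 log2. The lowest was that of NGB, the neuroglobin gene, at −0.78, although its other probe set differed by 0.13. LDLRAD2 followed at −0.71, ZNF605 at −0.68, TTC9 at −0.66, BMP8B at −0.65 and the cyclooxygenase gene PTGS2 at −0.63. OBP2B was at −0.62, the chemokine gene CCL24 at −0.62, ZNF594 at −0.59 and USP17L10 at −0.58. Of these genes LDLRAD2, TTC9, CCL24 and USP17L10 with CFX, and LCE4A and KLHDC7B in the control, lay below the floor, so the sizes of their differences are uncertain. Of the topoisomerase genes, TOP2A differed by 0.13 and TOP2B by 0.17 log2, and the 5 measured topoisomerases together had a median of 0.052 at percentile 85.7, which did not stand apart. ZNF836 and SPN were below the median of all probe sets in the control, so the sizes of their differences are uncertain as well, and 0 genes were 2-fold higher when the mean of the 3 arrays had to reach that level.

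With Mt-CFX, stress genes controlled by ATF4 were far higher than in the vehicle control, and genes of DNA replication and cell division were lower. The ATF4 list had a median of 0.69 log2 over 19 genes, and the aminoacyl-tRNA synthetases one of 0.49 over 17 genes. The list of G1/S and DNA replication genes had a median of −0.34 over 29 genes and the list of G2/M and mitosis genes one of −0.17 over 38 genes. Cholesterol biosynthesis genes were lower by a median of −0.16 log2. GDF15 was 7.09-fold higher and EGR1 8.82-fold higher at the probe set used, with a log2 difference of 1.64 at its other probe set, and the chemokine gene CCL2 was lower by the widest margin, to a value below the floor. At the 2-fold size, 27 genes were higher and 23 were lower.

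In the ATF4 list 16 of 19 members were higher with Mt-CFX, 0 were lower and 3 were equal, and 8 were at least 2-fold higher. The median lay above all 10000 random lists. GDF15 was higher by 2.82 log2, DDIT4 by 2.58, and TRIB3, a pseudokinase induced under stress, by 1.97. CTH was higher by 1.89 log2, DDIT3, which encodes the transcription factor CHOP, by 1.69, and SESN2, a stress-induced inhibitor of mTOR signalling, by 1.66. ATF4 itself was higher by 0.83. DDIT3 stood at 3.06 in the control, below the median of all probe sets, and at 4.75 with Mt-CFX, so the size of its difference is uncertain. Of the aminoacyl-tRNA synthetases 12 were higher, 2 were lower and 3 were equal, and their median also lay above all 10000 random lists. WARS1 was higher by 1.05 log2 at the probe set used and by 0.00 at its other probe set, SARS1 by 0.97, CARS1 by 0.79 and MARS1 by 0.78.

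**Figure D1:**
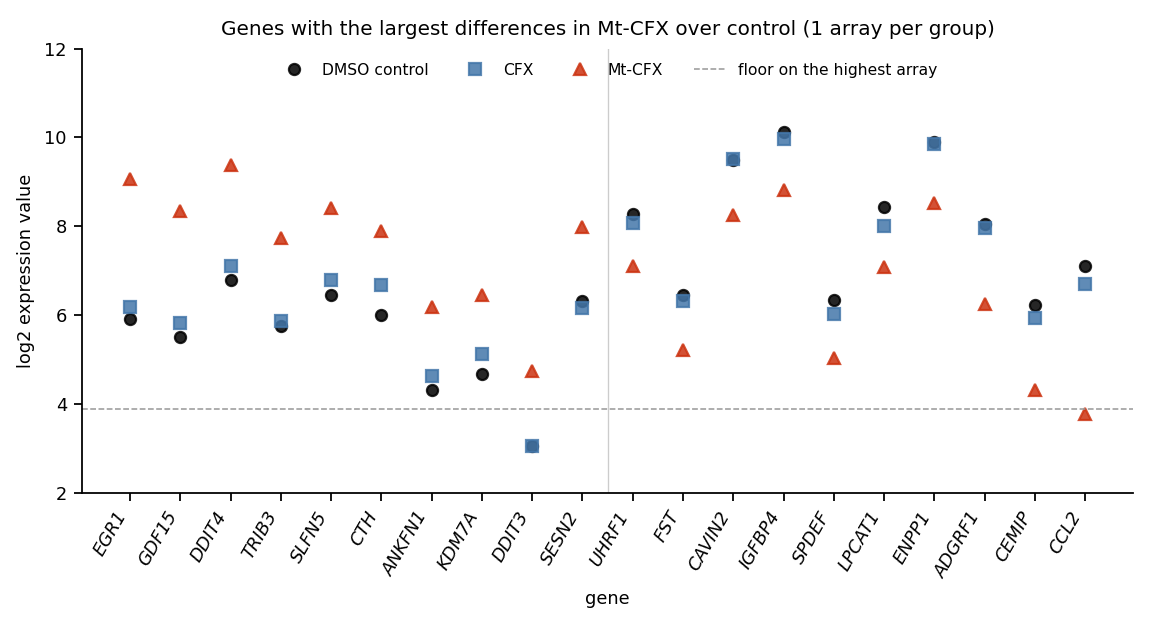
Log2 expression values (y axis) of the 10 genes with the highest and the 10 with the lowest log2 differences in Mt-CFX over control (x axis, ordered by the difference), with 1 point per array. The dashed line is the level that the highest of the 3 arrays had to reach, and EGR1 is at 5.92 in the control, 6.17 with CFX and 9.06 with Mt-CFX, CCL2 at 7.11, 6.70 and 3.76.

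Immediate early genes, which respond within minutes to growth factors and stress, had a median of 0.086 and a mean of 0.33 log2, with 18 of 24 members higher, 3 lower and 3 equal. EGR1 led them at 3.14 log2, while its other probe set differed by 1.64. MYC was higher by 0.88, IER2 by 0.84 and JUNB by 0.71. The lower members were JUN at −0.55, DUSP4 at −0.45 and DUSP6 at −0.08. Targets of NRF2, the regulator of antioxidant genes, had a median of 0.13 log2 at percentile 99.9, with 7 of 13 members higher, 1 lower and 5 equal. TXNRD1, which encodes thioredoxin reductase, was higher by 1.12, the autophagy receptor gene SQSTM1 by 0.84, NFE2L2, the gene for NRF2, by 0.63 and SRXN1 by 0.57, while HMOX1 had equal values on the 3 arrays. Cytosolic ribosomal protein genes had a median of 0.032 and a mean of 0.11 log2. Of 45 members 29 were higher, 0 were lower and 16 were equal, with RPS15A at 0.50, RPS27 at 0.46, RPL39 at 0.42 and RPL19 at 0.41. The other probe sets of RPL39 and RPL19 differed by 0.02 and 0.05.

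In the G1/S and DNA replication list 26 of 29 members were lower with Mt-CFX, 0 were higher and 3 were equal. The median lay below all 10000 random lists. UHRF1, which is needed to maintain DNA methylation after replication, had a log2 difference of −1.19. FEN1, a flap endonuclease of lagging strand synthesis, was at −1.14, the replicative helicase subunit GINS2 at −0.90 and the cyclin gene CCNE2 at −0.64. In the G2/M and mitosis list 30 of 38 members were lower, 0 were higher and 8 were equal, again with the median below all random lists. The proliferation marker MKI67 was at −0.60, and the mitotic kinesin genes KIF18B, KIF4A and KIF11 were at −0.56, −0.54 and −0.40. TOP2A was at −0.30 and CCNB1 at −0.14, while CDK1 and CCND1 had the same value with Mt-CFX as in the control.

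Metabolic lists stood apart as well. Of 17 cholesterol biosynthesis genes 14 were lower, 0 were higher and 3 were equal, with HSD17B7 at −0.75, INSIG1 at −0.65, ACAT2 at −0.55 and HMGCS1 at −0.45. Fatty acid synthesis genes had a median of −0.079 and a mean of −0.24 log2 over 12 members, of which 6 were lower, 2 were higher and 4 were equal. Their placement was lost with a floor on the mean of the 3 arrays. FASN was at −1.10, which is 0.468 of the control level, ACACA at −0.66, SCD at −0.50 at the probe set used and −0.12 at its other probe set, and FADS1 at −0.35. The TCA cycle list, which includes the pyruvate dehydrogenase complex, had a median of −0.12 log2 with 9 of 11 members lower and 0 higher. Lowest were OGDH at −0.36 and the pyruvate dehydrogenase subunits PDHB at −0.34, DLD at −0.31 (shared with the OGDH complex) and DLAT at −0.28. The other members were PDHA1 at −0.14, IDH3G at −0.12, IDH3B at −0.11, IDH3A at −0.07, CS at −0.02, and DLST and PC at 0.00. Heat shock genes had a median of −0.18 log2 over 9 members, of which 5 were lower and 1 was higher. HSPA1B was at −0.61, HSPA1A at −0.57, HSPH1 at −0.33 and HSPB1 at −0.31, and the near-identical sequences of HSPA1A and HSPA1B leave open how far their probes read the same transcripts. The TCA cycle and heat shock lists stood apart by their medians and not by their means, which lay at percentiles 1.33 and 0.790.

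**Figure D2:**
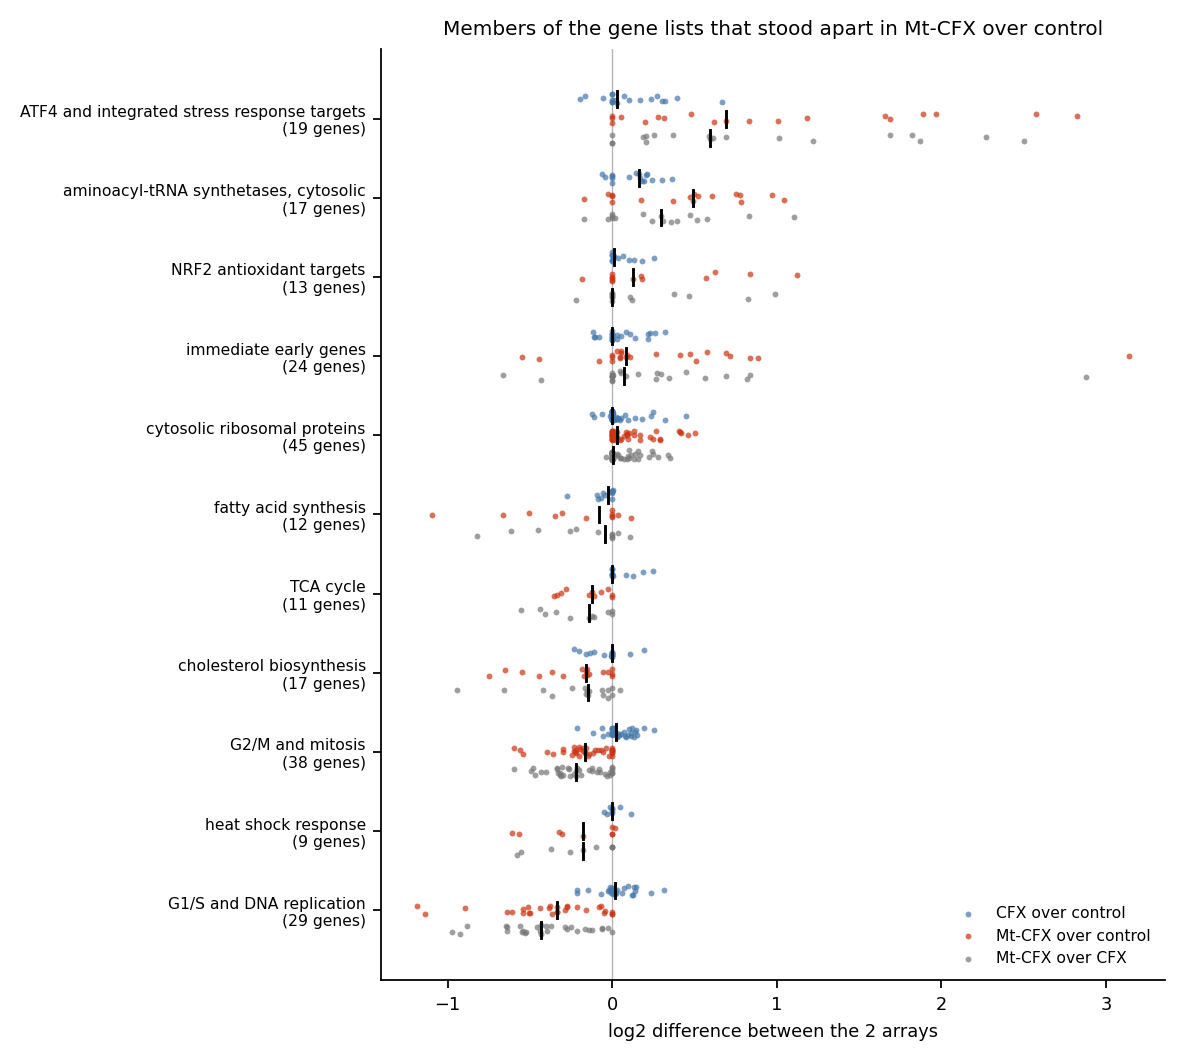
Log2 differences (x axis) of the members of the 11 gene lists (y axis) that stood apart in Mt-CFX over control, with 1 point per gene in each of the 3 comparisons and a vertical bar at each median. The points are spread in height for legibility, and the medians run from 0.69 for ATF4 targets to −0.34 for G1/S and DNA replication in Mt-CFX over control, against 0.031 and 0.017 for the same lists in CFX over control.

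The 10 highest differences also included SLFN5 at 1.96, ANKFN1 at 1.87 and the histone demethylase gene KDM7A at 1.77 log2. The lowest was that of CCL2, which attracts monocytes, at −3.35, from 7.11 in the control to 3.76 with Mt-CFX, which is below the floor of 3.89, so the size of the difference is uncertain. CEMIP, a gene of hyaluronan breakdown, was at −1.92, the adhesion receptor gene ADGRF1 at −1.81, the ectonucleotidase gene ENPP1 at −1.38 and LPCAT1, an enzyme of phospholipid remodelling, at −1.36. SPDEF was at −1.31, IGFBP4 at −1.29, CAVIN2 at −1.26 and FST, which encodes the activin antagonist follistatin, at −1.25.

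Several lists that did not stand apart by their medians held members with differences of 1.5-fold or more. The p53 target list had a median of 0.00 and a mean of 0.25 log2 at percentile 99.9, carried by SESN2 at 1.66, which is also in the ATF4 list, and by PMAIP1, the gene for the pro-apoptotic protein NOXA, at 0.84. Chaperones and sensors of the endoplasmic reticulum went both ways, with the chaperone CALR at −0.85, the transcription factor gene XBP1 at 0.82 and the sensor ERN1 at 0.60, and a median of 0.00 over 11 genes. In the extracellular matrix list THBS1 was at −1.14 and FN1 at −0.72, with a median of −0.021 and a mean of −0.23 log2 at percentile 0.310, while VIM was equal on the 3 arrays at the probe set used. Among NF-kB targets CSF1 was at −0.83, PTGS2 at 0.96 and TRAF1 at 0.63. The protease inhibitor gene TIMP3 was at −1.13 at the probe set used and −0.27 at its other probe set. MAP1LC3B, the autophagosome marker LC3B, was higher by 1.36, LDHA was at −0.73, CA12 at −0.63, AGR2 at −0.59, with its Mt-CFX value below the floor, and SFN at −0.69.

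Those mitochondrial lists that could be placed, other than the TCA cycle list with its pyruvate dehydrogenase members, did not stand apart with Mt-CFX. Mitochondrial ribosomal proteins had a median of 0.00 over 73 genes, of which 11 were higher, 26 were lower and 36 were equal. Of the 38 genes in the list of respiratory complexes II to V, 15 were measured, with a median of 0.00. All 15 belong to complexes III and IV, so complexes II and V had no measured member. Neither had the lists of 36 nuclear complex I subunits and 13 mitochondrially encoded genes, so nothing can be said about these. Mitochondrial chaperones and proteases had a median of 0.00 over 11 genes, and genes of mitochondrial DNA maintenance and expression one of 0.00 over the 11 measured of 25. Among genes of cell death BAX was at −0.11, BCL2L1 at 0.17 and BCL2 was equal on the 3 arrays. The 7 measured reference genes had a median of 0.00 and a mean of −0.014 log2. Interferon-stimulated genes had a median of 0.00 over 24 members, of which 9 were lower, 0 were higher and 15 were equal.

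Set directly against CFX at 10 µM and 72 h, Mt-CFX gave higher values of ATF4 targets by a median of 0.59 log2 and of aminoacyl-tRNA synthetases by a median of 0.30. G1/S genes were lower with Mt-CFX than with CFX by a median of −0.43 and G2/M genes by a median of −0.22. At the 2-fold size, 23 genes were higher with Mt-CFX than with CFX and 11 were lower. With 1 array per compound no interval of any of these differences can be given, and genes with like values on both arrays cannot be called alike in their response.

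EGR1 differed by 2.88 log2 between the compounds and by 1.54 at its other probe set, GDF15 by 2.50, DDIT4 by 2.27, TRIB3 by 1.87, SESN2 by 1.82, DDIT3 by 1.69, from a CFX value below the floor that leaves its size uncertain, and SLFN5 by 1.63. PTGS2 was higher by 1.59, ANKFN1 by 1.56 and STK32A by 1.54. The lowest differences were those of CCL2 at −2.94, with the same uncertainty of size, ADGRF1 at −1.73, CEMIP at −1.63, ENPP1 at −1.34, CAVIN2 at −1.27, SERTAD4 at −1.16, IGFBP4 at −1.14, FST at −1.11, LGR4 at −1.07 and LMO3 at −1.05.

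Between the compounds 9 lists stood apart. In the ATF4 list 16 of 19 members were higher with Mt-CFX, 0 were lower and 7 were at least 2-fold higher. Among aminoacyl-tRNA synthetases 12 of 17 were higher and 2 were lower, with WARS1 at 1.11 at the probe set used and 0.00 at its other probe set, SARS1 at 0.83, CARS1 at 0.57 and GARS1 at 0.51. Immediate early genes had a median of 0.069 log2, with IER2 at 0.84, JUNB at 0.82 and ATF3 at 0.69. Of 24 members 15 were higher, 7 were equal and 2 were lower, DUSP4 at −0.67 and JUN at −0.43. Ribosomal protein genes had a median of 0.0057, with 23 of 45 members higher, 1 lower and 21 equal. Of the 29 G1/S genes 28 were lower with Mt-CFX than with CFX and 1 was equal, with UHRF1 at −0.97, FEN1 at −0.92, GINS2 at −0.88 and TYMS at −0.64. Of the G2/M genes 33 of 38 were lower and 0 were higher, with MKI67 at −0.60, KIF18B at −0.50, ECT2 at −0.48 and KIF11 at −0.47, and TOP2A was at −0.43. The TCA cycle list had a median of −0.14 log2, with OGDH at −0.44 and the pyruvate dehydrogenase subunits DLD at −0.56 and DLAT at −0.41. Cholesterol biosynthesis genes had a median of −0.15, with HSD17B7 at −0.94 and ACAT2 at −0.66. Heat shock genes had a median of −0.18 at percentile 0.450 and a mean at percentile 0.690, so that they stood apart by the median alone.

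Genes outside these lists that differed by at least 1.5-fold between the compounds included DNA2, a nuclease and helicase of nuclear and mitochondrial DNA, at −0.66, the p53 target EDA2R at 0.93 and the matrix gene TNC at 0.65. TXNRD1 was higher with Mt-CFX by 0.99 and SQSTM1 by 0.83, FASN was at −0.82 and ACACA at −0.62. NRF2 targets, p53 targets and fatty acid synthesis genes did not stand apart by their medians between the compounds, at 0.00, 0.00 and −0.044 log2, and stood apart by their means, at 0.20, 0.23 and −0.19 log2.

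The differences from the control were then compared between the compounds. No protein-coding gene above the floor was 2-fold different in the same direction with both. At 1.5-fold, BEND7 and CTH were higher with both compounds. BMP8B, CCL24 and TTC9 were lower with both (CCL24 and TTC9 to values below the floor). Independent lists of these sizes would share 0.0582 and 0.113 genes, but the lists share the control array, so these are not values for no effect. BMP8B and CCL24 were exactly equal on the CFX and Mt-CFX arrays, at 4.40 and 3.86, so a single control value sets both of their differences. Simulated arrays with a shared control and no effect gave 0 genes 1.5-fold the same way. They had no ties and the same SD for every gene, so they set no firm value either. Of the 27 genes that were 2-fold higher with Mt-CFX, 19 were also above the control with CFX, 5 were below it and 3 were equal to it, with a median of 0.14 log2 with CFX against 1.36 with Mt-CFX. Of the 23 genes that were 2-fold lower with Mt-CFX, 20 were also below the control with CFX, 2 were above it and 1 was equal, with medians of −0.21 and −1.17 log2. The counts among the 27 and the 23 genes share the control array and have no value for no effect beside them, so they do not measure a shared response. Across genes, which are not independent replicates, Pearson's r between the 2 sets of differences was 0.423 and Spearman's rho 0.401.

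Both sets of differences used the same control array, which makes them correlate with no effect at all. In simulated arrays with no effect, r was 0.501 and the covariance 0.00445, against an observed covariance of 0.00843. The simulation gave each array the same SD, and a noisier control array would give a larger covariance with no effect. The control cannot be split, so part or all of the agreement between the compounds may come from the shared array. PTGS2 was the gene with differences of at least 1.5-fold in opposite directions, at −0.63 log2 with CFX and 0.96 with Mt-CFX.

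**Figure D3:**
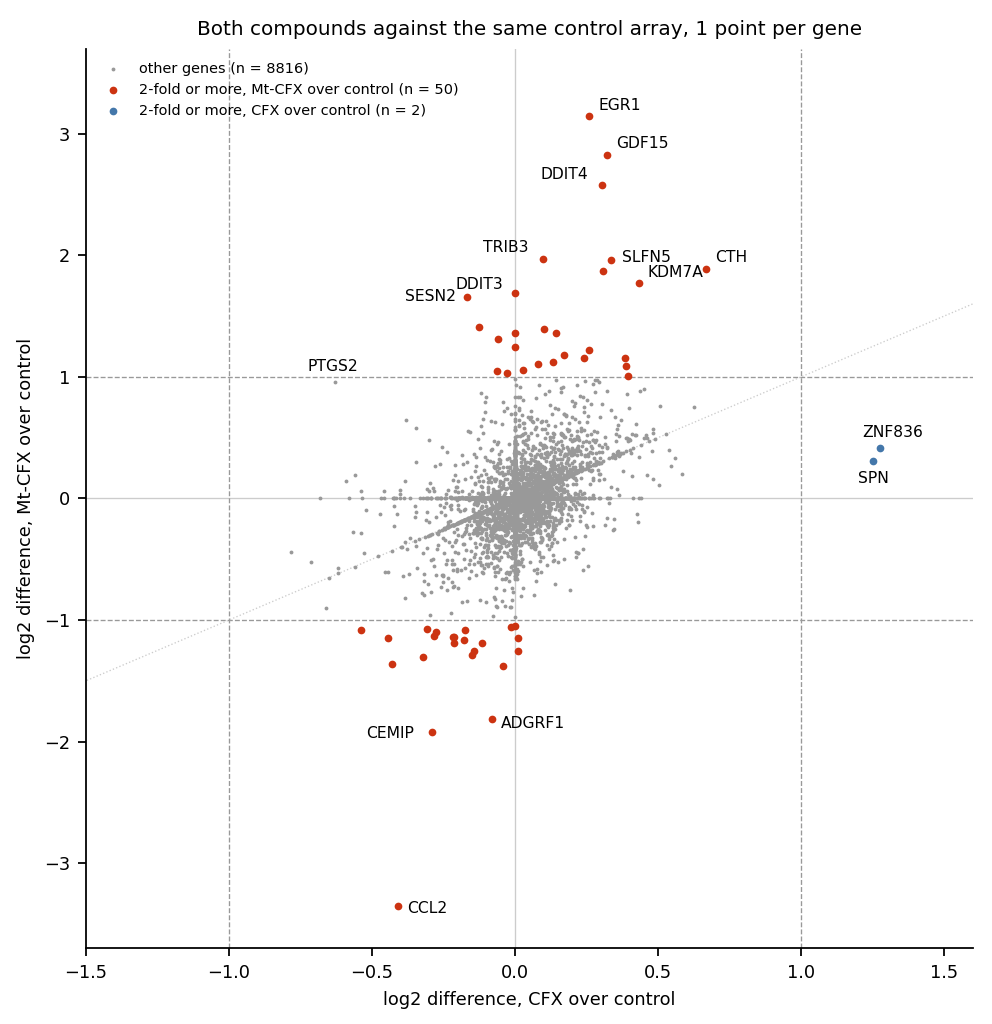
Log2 difference of each of the 8868 genes in CFX over control (x axis) and in Mt-CFX over control (y axis), with 1 point per gene. Dashed lines mark 2-fold and the dotted line equal differences, the axes have different scales, the 50 genes at least 2-fold different with Mt-CFX lie between −3.35 and 3.14 on the y axis, and the 2 genes at least 2-fold different with CFX, ZNF836 and SPN, lie to the right.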

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

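The tests for a floor on low values, for a control array that alone read low or high, for Mt-CFX RNA in the CFX sample, for an intensity-dependent difference and for a fault of the Mt-CFX array were chosen only after the results were seen.

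PTGS2, the gene for cyclooxygenase, went in opposite directions with the compounds, at −0.63 log2 with CFX and 0.96 with Mt-CFX against the same control array. Each value rests on 1 array, and the difference between them was not tested. Probe sets without a gene symbol, which no comparison of genes used, also differed between arrays, and 16805 of them passed the floor. At least 2-fold higher were 228 in CFX over control, 214 in Mt-CFX over control and 167 in Mt-CFX over CFX. At least 2-fold lower were 196, 263 and 276. Their share past 2-fold was 2.52% with CFX against 0.0226% of the named protein-coding genes, 2.84% with Mt-CFX against 0.564%, and 2.64% between the compounds against 0.383%. The units are unlike, since every unnamed probe set was counted, but each gene only by its probe set of highest mean. The unnamed share was similar in the 3 comparisons and was not checked against the spread between repeats, so it is no count of responding transcripts.

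The first pattern is the large share of exactly equal values. A floor on low values as the only cause is argued against by the genes with the highest expression, above the 75th percentile of those compared, of which 24.2% were equal on all 3 arrays. Of those below the 25th percentile 62.7% were equal, so a part played by low values stays open there. In simulated probe sets of 25 probes with no effect and a probe SD of 0.25 log2, a median polish over 3 arrays left 78.3% equal on all 3. In the data exact ties outnumbered differences under 0.01 log2 by 26.3 times. The ties may come from the summary step, with a simulated true difference of 0.2 log2 returned as a median of 0.066. The share was lower with fewer simulated probes, at 0% with 4, and the number of probes per probe set was not used here. Different genes also shared exact values in the control, such as MAP1LC3B and ATF3 at 4.0791, and SRXN1 and CCNE2 at 6.2897. Simulated probe values were continuous and would not give this, so the simulation cannot decide where the ties come from. No biological explanation of the ties was tested.

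The second pattern is the graded level of the aminoacyl-tRNA synthetases, higher with CFX than in the control and higher again with Mt-CFX. A control array that alone read low for these genes would leave the compounds level, but Mt-CFX lay above CFX by a median of 0.30 log2. For the step from control to CFX, 0.16 log2, such a control cannot be told apart from an effect of CFX, because the design has 1 control array and the labels give a DMSO content for it alone. If Mt-CFX RNA mixed into the CFX sample gave these 17 genes their median, it would make up 29.5% of it, and the 26 other genes at least 2-fold higher with Mt-CFX would be higher with CFX by a median of 0.55 log2 (lower quartile 0.45), but they were higher by 0.16 (upper quartile 0.32), with 25 of 26 below the prediction. An effect of CFX stays open as a hypothesis, although WARS1 and SARS1, the synthetases highest with Mt-CFX, had CFX excesses of −3.92% and 10.9% of the Mt-CFX excess. The 12 synthetases above the control with Mt-CFX ran from −3.92% to 116% (LARS1), with a median of 29.5%. For 783 other genes with Mt-CFX differences in the same range the median was 23.0% and the quartiles were 0% and 60.2%, a spread that holds the synthetases' median.

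The third pattern is the lower level of cell cycle genes with Mt-CFX. A control array that alone read high is argued against by the G1/S median of −0.43 log2 in Mt-CFX over CFX. An intensity-dependent difference between arrays would lower other genes of the same expression alike, but these averaged 0.0013 log2 against a G1/S mean of −0.38. The lowest mean of 10000 matched random lists was −0.20. These random lists were the ones that had placed the G1/S list, so their range repeats that placement and is no further test. The planned test, re-centring by a lowess curve, moved no gene in Mt-CFX over control and so tested nothing. A fault of the Mt-CFX array or culture, such as a denser or poorer plate, cannot be told apart from an effect of Mt-CFX on proliferation, which stays open and untested, since 26 of 29 G1/S members were lower than on both other arrays and there was 1 Mt-CFX array.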

How the results depend on the processing

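All alternatives were planned, except that the overlap of the compounds over genes of every type was added after the data were seen, and none reversed a direction that had been called. Of the lists that stood apart, 2 of 6 in CFX over control, 8 of 11 in Mt-CFX over control and 8 of 9 in Mt-CFX over CFX did so in the same direction under each of 7 alternatives (re-centring, 1 of these, moved genes by at most 0.0334 log2 and none in Mt-CFX over control, so it tested little), including the aminoacyl-tRNA synthetases in all 3 comparisons and the ATF4, G1/S, G2/M, immediate early and cholesterol lists in both comparisons of Mt-CFX. The causes of the changes below were not tested. With CFX, 0 genes were 2-fold higher under a floor on the mean of the arrays and 0 under a floor at the 75th percentile, since ZNF836 and SPN are expressed at low levels. Over genes of every type with 1 symbol, each still read by its 1 probe set of highest mean, 6 were higher and 1 lower, and with no floor 1 was lower. At 1.5-fold, 4 genes were higher and 9 lower with CFX, 129 and 111 with Mt-CFX, and 100 and 91 in Mt-CFX over CFX. Genes different the same way with both compounds numbered 1 with no floor (GH1), 1 over genes of every type (MIR29A, with a control value below the floor) and 5 at 1.5-fold; GH1 and MIR29A are named after their values were seen. In CFX over control the ATF4 list no longer stood apart with no floor (median 0.020 log2) or with the mean of a gene's probe sets (0.031), and the glycolysis list with re-centring (−0.029). By list means, the DNA damage (0.059), glycolysis (−0.037) and hypoxia (−0.040) lists no longer stood apart with CFX, nor the heat shock (−0.22) and TCA cycle (−0.16) lists with Mt-CFX, nor the heat shock list (−0.23) in Mt-CFX over CFX. The heat shock list in Mt-CFX over CFX was also lost with no floor and with a floor on the mean of the arrays, each with a median of −0.18, and fatty acid synthesis with Mt-CFX under a floor on the mean of the arrays (−0.079). With the mean of a gene's probe sets WARS1 was at 0.52 with Mt-CFX and 0.55 in Mt-CFX over CFX, and TIMP3 at −0.70 with Mt-CFX, all within 2-fold, and the log2 difference of EGR1, Mt-CFX over control, was 2.39, below that of GDF15 at 2.82. The correlation of the 2 compounds' log2 differences lay between 0.401 (Spearman's rho) and 0.445 (floor at the 75th percentile). The number of arrays, 1 per group, limits every value.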

Other observations

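The test of the endoplasmic reticulum list in this part was chosen only after the result was seen, and the genes named here outside the last paragraph were picked after their values were seen.

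Adhesion G protein-coupled receptors, a family of large cell surface receptors, were looked at because ADGRF1 was among the lowest genes, and they are not 1 of the fixed lists, so their values show only that group as found. Of 13 members above the floor 9 were lower than in the control, 0 were higher and 4 were equal, with a median of −0.16 log2, where 23.2% of all genes and 25.6% of genes of the same expression were lower. ADGRF1 was at −1.81, ADGRF5 at −1.17 and ADGRG1 at −1.15, and with CFX the same genes were at −0.08, −0.18 and −0.44. With CFX 6 members were lower, 1 was higher and 6 were equal, where 14.8% of genes of the same expression were lower. Between the compounds 9 members were lower with Mt-CFX and 0 were higher, where 29.0% of genes of the same expression were lower.

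Non-coding RNA probe sets were not part of the gene comparisons. With Mt-CFX 8 of 494 microRNA probe sets above the floor were at least 2-fold higher and 3 were lower, and 3 of 638 long non-coding RNA probe sets were higher and 0 were lower. With CFX 3 microRNA probe sets were higher and 3 were lower, and 1 long non-coding RNA probe set was higher and 0 were lower. MIR29A was higher with both compounds, by 1.54 and 1.67 log2, from 1 shared control value below the floor, so neither the sizes nor their likeness can be relied on. Its neighbour MIR29B1 differed by 0.00 with Mt-CFX. MIR503 was higher by 1.70 log2 and its neighbour MIR424 by 0.82, while the neighbours MIR542 and LINC00629 differed by 0.00. CRNDE was higher by 1.11 log2, while its neighbour IRX5 differed by 0.00. MIR3189, which lies within GDF15, was higher by 1.31 and GDF15 by 2.82, NHSL1-AS1 by 1.54 and the overlapping NHSL1 by 0.30, and VLDLR-AS1 by 1.28 and the overlapping VLDLR by 0.28. MIR3189, NHSL1-AS1 and VLDLR-AS1 were below the floor in the control, so the sizes of their differences are uncertain. MIR100 was higher by 1.11 while the overlapping MIR100HG differed by 0.00, and MIR924 was at −1.35 and the overlapping MIR924HG at −0.22. These probe sets read whole-transcript cDNA, so the values need not be those of mature microRNAs.

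A hypothesis is that the ATF4 targets were higher with Mt-CFX under a stress other than unfolded protein in the endoplasmic reticulum. It would need the reticulum's own list to stay level, and the mean of that list lay at percentile 58.9 in Mt-CFX over control. Only 11 of its 22 genes were measured, of which 4 were higher, 5 were lower and 2 were equal. Higher were XBP1 at 0.82, the sensors ERN1 at 0.60 and ATF6 at 0.29, and SEL1L at 0.44. Lower were CALR at −0.85, MANF at −0.56, SDF2L1 at −0.52, HYOU1 at −0.10 and CANX at −0.02. None of the chaperones measured was higher, but HSPA5 and HSP90B1 were not measured. The data may therefore be read either way and do not decide it.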
